A study of Arabidopsis thaliana with 6 samples.

How the data were processed

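Gene expression was measured in inflorescences of *Arabidopsis thaliana*, the shoot tips that carry flower buds and open flowers. Total RNA was labelled with biotin and hybridised to an Affymetrix array of 22810 probe sets, where each probe set is a group of short DNA probes that reads out the transcript of 1 gene or of a few similar genes. There were 3 arrays of the wild type, the accession Landsberg erecta, and 3 arrays of the mutant *top1α-2*. Genotype and replicate number were taken from the labels, and the series describes the replicates as biological.

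The deposited values are log2 signals, 1 column per array. Per the submitters' processing notes they were made with affy and MAS5, a method that corrects the background within each array and combines the probes of a probe set into 1 signal. Versions and any filter are not given in the sources used here. The values themselves show the scaling: the mean of the unlogged signal without the 2% highest and 2% lowest probe sets was 500 on every array. Detection calls were not used here, so a low signal is given as a signal and not as absence. For arrays, precision is limited by their number, which was 3 per genotype.

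From these values the 64 control probe sets were set aside, and the remaining 22746 were tested with limma 3.58.1 in R 4.3.3. The model held genotype alone, was fitted with lmFit and eBayes with a variance prior that follows the signal, and was adjusted by the Benjamini-Hochberg method over all probe sets. A probe set with an adjusted p under 0.05 is called higher or lower. No further normalization, pseudocount or filter on dim probe sets was used. Differences are *top1α-2* minus wild type on the log2 scale, with the standard error of the fit, and group means are given with their SD over 3 arrays.

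The platform annotation used here names 1 gene for 13513 probe sets and several genes for 503, and the other 8730 are unnamed here. By gene identifier, 13436 of the single-gene probe sets matched the RefSeq gene table of assembly TAIR10.1, which gave current symbols and AGI locus codes and no coordinates. For a gene with more than 1 such probe set, of which there were 146, that with the highest mean signal was used, which left 13356 genes. In 0 of those 146 genes were probe sets called in opposite directions.

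The probe sets of *TOP1α* and its neighbour *TOP1β* are unnamed here, so the level of the mutated gene was not analysed here and gives no check of the labels. Many widely studied floral regulators, such as *AG*, *WUS* and *STM*, were not analysed here for the same reason. A trend of change with gene length was planned and not run, because no array build is named for which gene spans could be taken.

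Gene lists were of 2 kinds. Lists fixed before the data were examined held 320 loci, of which 39 had a single-gene probe set. Lists of transposable elements, cytosolic ribosomal proteins and core histones were matched by text in gene symbols and synonyms and gave 0, 0 and 3 genes. Titles, descriptions and gene types, which the plan named, were not searched. The counts of 0 therefore do not show that such genes are absent from the array. The 6 fixed lists with at least 3 measured members were tested. Because so few fixed members could be measured, 25 further lists were drawn up from the gene names after the annotation was seen and before any test was run. They are called added lists. The result of 1 added list is not reported here. The values of the first few probe sets, among them that of the mitochondrial gene *nad4L*, had been seen by then.

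Lists were tested with camera in limma, which compares the change of a list with that of all other genes, at a preset inter-gene correlation of 0.01. Adjustment was over the lists of each kind. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in a single direction and makes no comparison with other genes, were alternatives.

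The genes named were chosen by a rule set before the data were examined. It took up to 12 genes with the highest and 12 with the lowest log2 change among single-gene probe sets that were called, whose 3 against 3 values did not overlap, and whose higher group mean lay above the median of all probe sets. It added members of fixed lists past the threshold over all genes or over the list alone, and up to 3 members of each fixed list with the smallest p. Genes of the added lists, neighbouring genes and the actin control probe sets were chosen after their values were seen. Probe sets of near-identical genes can share signal, so members of gene families carry that uncertainty.

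On simulated data with the means and spread of these arrays, 200 of the 22746 probe sets were changed by known amounts, 25 for each size. The changed probe sets were drawn only from those with a mean signal above the median. Each probe set was simulated independently of the others. Recovery among dimmer probe sets or correlated genes was therefore not measured. The real comparison called 2107 probe sets, many more than the 200 changed here. The Benjamini-Hochberg cutoff is stricter when fewer probe sets change, so recovery in the real comparison can differ from that given here. The simulated comparison of *top1α-2* with the wild type recovered 100% of those lowered by 2 log2 units, 84% of those lowered by 1 and 20% of those lowered by 0.5. It recovered 88% of those raised by 1 and 8% of those raised by 0.5. Among the 22546 unchanged probe sets, 6 were called.

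Alternatives tried were quantile normalization, centring each array on its median, a pseudocount of 16, leaving out the dimmest 25% or 50% of probe sets, the replicate number as a block, leaving out each array in turn, a variance prior without the trend, a plain test per probe set, other thresholds, other set tests and other windows around the mutated locus.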

Results

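The series compared gene expression in inflorescences of *top1α-2*, a mutant in a gene for DNA topoisomerase 1, with that in wild-type plants of the accession Landsberg erecta. DNA topoisomerase 1 relaxes the supercoils that form when DNA is transcribed or copied. The comparison asks which transcripts depend on this enzyme in developing flowers. Each genotype was measured on 3 arrays, and the values are log2 MAS5 signals for 22746 probe sets. Across the 11369 brighter probe sets, arrays correlated at 0.955 to 0.977 within the wild type, 0.978 to 0.985 within *top1α-2* and 0.887 to 0.938 between the genotypes. As a measure of RNA quality, the 3′ signal minus the 5′ signal of an actin control was 3.57 ± 0.19 in the wild type and 4.03 ± 0.07 in *top1α-2* (SD, n = 3), without overlap, and the 5 other control ratios overlapped. A second actin control had means of 0.70 in the wild type and 0.74 in *top1α-2*. Means for GAPDH and ubiquitin lay between −0.15 and 0.63, so the large value was particular to the first actin control.

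Of 22 measured genes of pollen and the pollen tube, 15 fell and 0 rose in *top1α-2* inflorescences, and of 11 genes of the anther and tapetum, 5 fell and 0 rose. Of 25 measured nuclear genes for photosynthesis, 6 rose, 0 fell and 19 were not called. As groups, these 3 lists changed by camera with its preset correlation and not with an estimated one, where the adjusted p = 0.306, 0.12 and 0.405. By fry the adjusted p was 0.0164, 0.00134 and 0.0826. Estimated correlations were 0.55, −0.04 and 0.67, so for the anther and tapetum list a higher correlation did not end the call. The orphan gene *QQS*, which affects starch content, was 31.6-fold higher, and AT1G58025, which encodes a bromodomain protein, was 17.1-fold higher. By limma with an adjusted p under 0.05, 773 probe sets were higher and 1334 were lower, and among named genes 395 were higher and 723 lower.

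*QQS* had a mean of 6.53 ± 0.85 in the wild type and 11.52 ± 0.07 in *top1α-2* (SD, n = 3), a log2 change of 4.98 with an SE of 0.32 and a limma adjusted p of 2.49e-05. AT1G58025 rose from 7.48 ± 0.40 to 11.58 ± 0.26, with a limma adjusted p of 1.14e-05. Genes for peroxidases, which act on cell walls and reactive oxygen, were among the 12 highest: AT5G19880 rose by 3.24, AT4G11290 by 2.02 and AT3G03670 by 1.82 on the log2 scale. The pectate lyase genes AT3G27400 and AT5G63180 rose by 2.36 and 2.01, and AT3G15720, a gene of the pectin lyase-like family, rose by 2.22. The dioxygenase gene *2A6* rose by 2.16 and the protein kinase gene AT5G11410 by 3.26. The other named increases were 1.84 for AT5G05960, of the lipid transfer protein family, and 1.77 for AT2G33850. In these 12 genes the 3 *top1α-2* values lay above the 3 wild-type values, a condition of their choice.

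**Figure D1:**
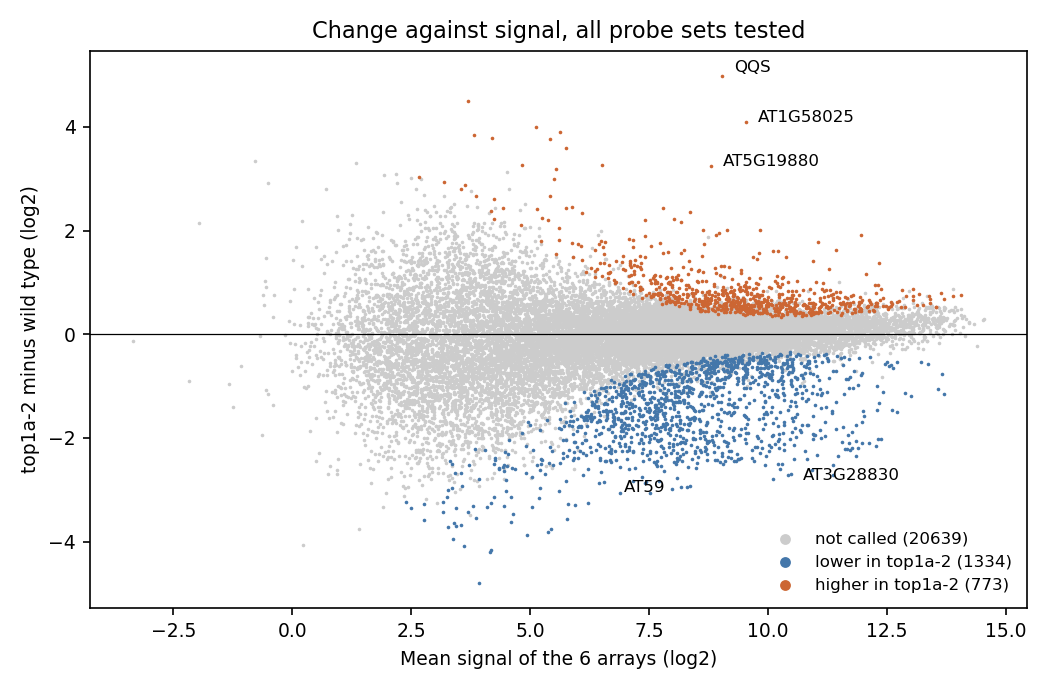
Each point is a probe set, with its mean log2 signal over the 6 arrays on the horizontal axis and the log2 difference of *top1α-2* minus wild type on the vertical axis. The 773 probe sets called higher and the 1334 called lower by limma are coloured, and QQS at 4.98 and AT59 at −2.93 are among those labelled.

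Among called single-gene probe sets whose genotypes did not overlap and whose wild-type mean lay above the median of all probe sets, the 12 lowest changes were between −3.07 and −2.58 on the log2 scale. *AT59*, a pectate lyase gene active in pollen, fell from 9.83 ± 0.52 to 6.90 ± 0.13 (SD, n = 3), with a limma adjusted p of 5.46e-05. AT1G29140, of the family of the olive pollen allergen Ole e 1, fell from 11.56 ± 0.61 to 8.95 ± 0.33. AT5G62750 fell by 3.07, and AT1G03050, which encodes a clathrin assembly protein, fell by 3.06. The tetraspanin gene *TET15* fell by 2.76 and the protein kinase gene AT3G20530 fell by 2.84. AT3G28830 and AT3G28980 were bright in the wild type, at 11.82 ± 0.71 and 12.23 ± 0.59, and fell by 2.69 and 2.61. The remaining decreases were −2.98 for AT5G26060, −2.94 for AT2G29790, −2.83 for AT2G17845 and −2.58 for AT1G04670.

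The added list of pollen and pollen tube genes had a median log2 change of −1.65, and its camera adjusted p was 2.08e-15. This call was lost with an estimated correlation, at an adjusted p = 0.306. By fry the adjusted p was 0.0164. The genes of the LIM proteins *PLIM2a* and *PLIM2b*, which bind actin in pollen, fell by 2.2 and 1.52. The receptor kinase gene *ANX2*, which keeps the growing pollen tube intact, fell by 2.26, and *MGH3*, which encodes a histone of the male germ line, fell by 2.24. The genes of the pollen transcription factors *AGL30*, *AGL66* and *AGL104* fell by 1.7, 1.92 and 1.77, and those of the myosins *XIC* and *XIE* by 1.34 and 2.05. With single arrays left out the limma adjusted p reached 0.0703 for *AGL30* and 0.0882 for *AGL104*. The list mean was 6.57 ± 0.05 in *top1α-2* and 8.10 ± 0.53 in the wild type (SD, n = 3). Wild-type replicate 1 stood apart from the other wild-type arrays, at 8.69 against 7.66 and 7.94.

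The anther and tapetum list had a median of −1.19 with a camera adjusted p of 5.25e-05 and, with an estimated correlation, an adjusted p = 0.12. That correlation was −0.04, and by fry the adjusted p was 0.00134. *ATA27* and AT5G07230, known as *A9*, are markers of the tapetum, the cell layer that feeds developing pollen, and they fell by 1.19 and 1.04. *SPL*, which is needed to start the formation of spore mother cells, fell by 1.46. *BZIP34*, a transcription factor of pollen wall formation, fell by 1.78, and the sugar transporter gene *SWEET8* by 1.57, the last with a limma adjusted p of up to 0.0556 with single arrays left out. *AMS*, a tapetum regulator, had a log2 change of −0.95 with a limma adjusted p of 0.0671. The list mean was 7.86 ± 0.08 in the wild type and 6.81 ± 0.12 in *top1α-2* (SD, n = 3).

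Nuclear genes for photosynthesis had a median change of 0.51 with a camera adjusted p of 2.9e-11, and all 25 had a positive log2 difference. With an estimated correlation their adjusted p = 0.405, and by fry 0.0826. *LHCB4.2*, of an antenna protein of photosystem II, rose by 0.79, *PORB*, of chlorophyll synthesis, by 0.76, and *PSBW*, of a photosystem II subunit, by 0.58. The calcium sensor gene *CaS* rose by 0.78. With single arrays left out *LHCB4.2* kept its call, while the limma adjusted p reached 0.0916 for *PORB*, 0.0809 for *PSBW* and 0.0723 for *CaS*. The list mean was 11.17 ± 0.27 in the wild type and 11.67 ± 0.08 in *top1α-2* (SD, n = 3), and wild-type replicate 1, which had the highest pollen list mean, had the lowest photosynthesis mean, at 10.87. Without that array the median was 0.34. Of 69 genes encoded in the plastid, 8 rose and 0 fell, among them *ndhA* by 0.85, *rpoC1* by 0.80 and *psbH* by 0.59, and with single arrays left out the limma adjusted p of the last 2 reached 0.0554 and 0.0893. Their median was 0.40 with a camera adjusted p of 2.97e-08, and 0.24 without wild-type replicate 3. With an estimated correlation their adjusted p = 0.405, and by fry 0.154. Array means of this list overlapped between the genotypes, at 9.21 to 9.71 in the wild type and 9.53 to 10.09 in *top1α-2*.

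**Figure D2:**
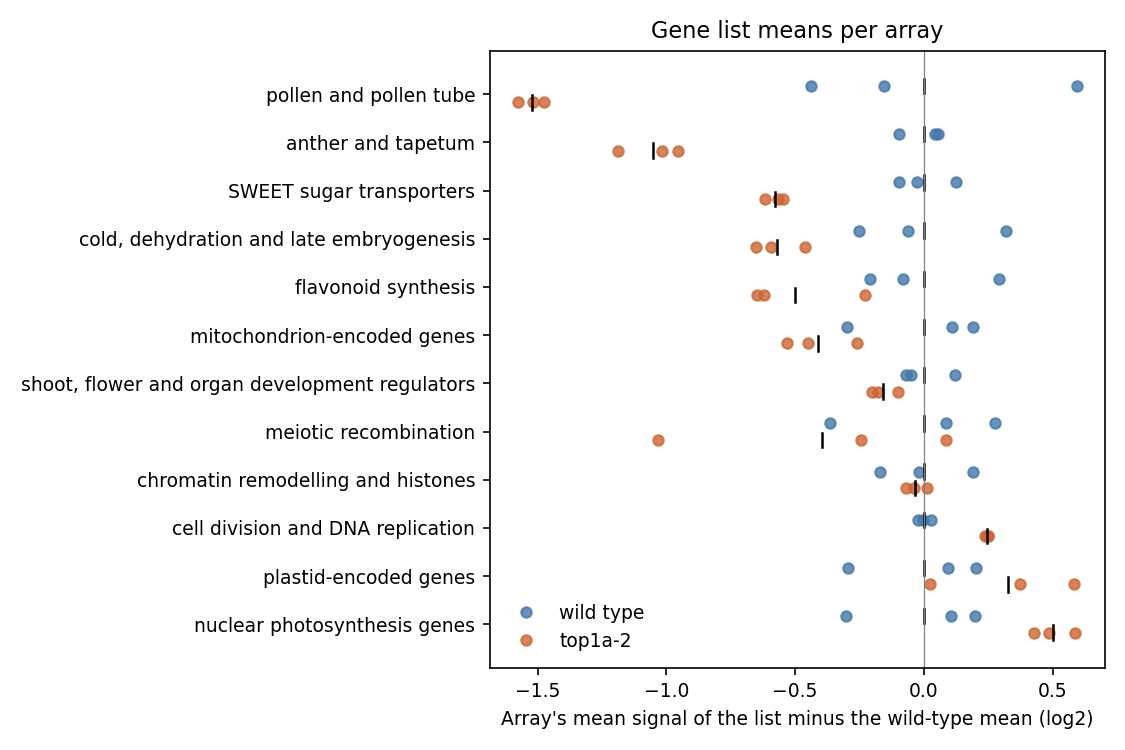
Points give the mean log2 signal of each gene list on each array, minus the mean of the 3 wild-type arrays, with 1 row per list and genotype, and black bars mark the genotype means. The pollen and pollen tube list lies lowest in top1α-2, and the nuclear photosynthesis list lies above the wild type on all 3 top1α-2 arrays.

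Of 24 genes of cell division and DNA replication, 4 rose and 1 fell, with a median of 0.23 and a camera adjusted p of 0.000672. The adjusted p with an estimated correlation was 0.12. That correlation was −0.04, and by fry the adjusted p was 0.00134. The genes that rose were *BUB3.2* by 0.83 and *Haspin* by 0.76, both of chromosome segregation, *ICU2*, of a DNA polymerase subunit, by 0.58 and the cell cycle gene *CKS* by 0.51. The microtubule gene *ATMAP65-6* fell by 0.65. Each of the 4 increases lost its call when any of 5 of the 6 arrays was left out, with limma adjusted p values of up to 0.157, and without the dimmest 50% of probe sets the list had a camera adjusted p of 0.102. With the replicate number as a block *ICU2* and *BUB3.2* lost their calls, at limma adjusted p values of 0.0623 and 0.0616. A pseudocount of 16 ended those of *ICU2* and *CKS*, at 0.051 and 0.0501. The array means of the cell division list were 8.29 ± 0.02 in the wild type and 8.54 ± 0.01 in *top1α-2* (SD, n = 3).

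Of 14 SWEET sugar transporter genes, 6 fell and 0 rose, with a median of −0.46 and a camera adjusted p of 0.000107 and, with an estimated correlation, an adjusted p = 0.12. By fry the adjusted p was 0.00791. *SWEET14* fell by 1.61, *SWEET7* by 1.41 and *SWEET13* by 1.06, the last with a limma adjusted p of 0.0543 when 1 array was left out. Among 16 genes of cold, dehydration and late embryogenesis, *LEA*, *COR47* and *LEA18* fell by 2.23, 1.00 and 1.91, while *DI21* and *HVA22C* rose by 0.54 and 0.55. That list had a median of −0.59, a camera adjusted p of 0.0155 and, with an estimated correlation, an adjusted p = 0.261. By fry the adjusted p was 0.0164. Of 16 genes encoded in the mitochondrion, *matR*, *nad9* and *cox2* fell by 3.14, 0.83 and 0.97. Their median was −0.38 with a camera adjusted p of 0.0194 and, with an estimated correlation, an adjusted p = 0.405. By fry the adjusted p was 0.0389. The median was −0.73 at a camera adjusted p of 0.00418 without wild-type replicate 3. Without the dimmest 50% of probe sets the median was −0.10 at an adjusted p of 0.597, and *matR* was dim in *top1α-2*, at 2.66 ± 0.51 (SD, n = 3). Of 8 genes of flavonoid synthesis, *UF3GT* fell by 1.21, and the list had a median of −0.46 with a camera adjusted p of 0.0408 and, with an estimated correlation, an adjusted p = 0.405. By fry the adjusted p was 0.137. With single arrays left out, the camera adjusted p of these last 3 lists reached 0.0573 for cold and dehydration, without *top1α-2* replicate 2, 0.0876 for the mitochondrion, without wild-type replicate 2, and 0.208 for flavonoids, without wild-type replicate 1. Without the dimmest 50% of probe sets it was 0.0942 for cold and dehydration and 0.0803 for flavonoids. Among the genes of these 3 lists, *UF3GT*, *LEA18* and *cox2* each lost their call when any of 5 of the 6 arrays was left out, with limma adjusted p values of up to 0.138, 0.117 and 0.0791, and after quantile normalization at 0.0588, 0.0554 and 0.0511. With a pseudocount of 16 *UF3GT* had 0.058. By contrast *LEA*, *COR47* and *matR* kept their calls with each array left out. *DI21*, *HVA22C* and *nad9* lost theirs without some arrays, at up to 0.0804, 0.118 and 0.0521.

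**Figure D3:**
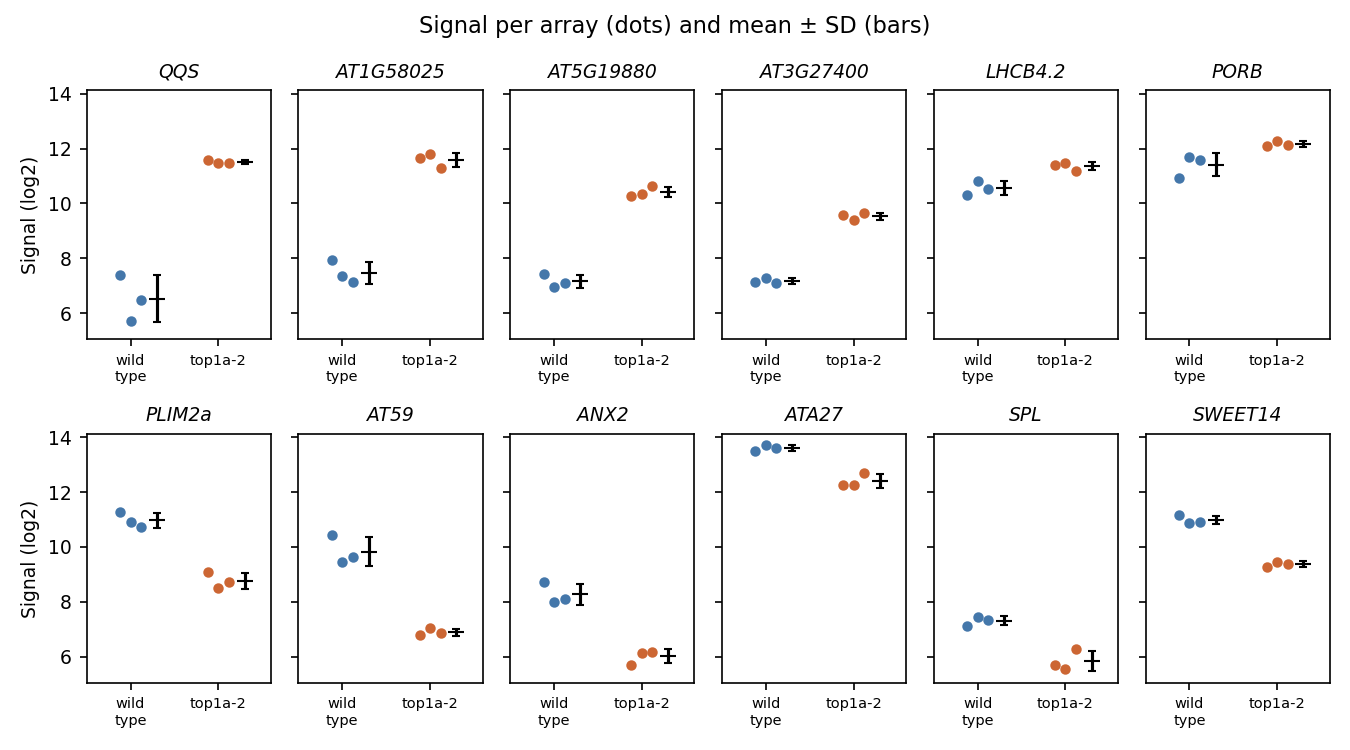
Dots give the log2 signal of 12 genes on each of the 3 wild-type and 3 top1α-2 arrays, and bars give the mean ± SD of each genotype. QQS lies near 6.53 in the wild type and 11.52 in top1α-2, while PLIM2a, AT59, ANX2, ATA27, SPL and SWEET14 lie lower in top1α-2.

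Of the lists fixed before the data were examined, 1 of the 6 tested changed by camera. This was maturing pollen, whose 4 measured members all fell, both over all genes and adjusted over the list alone. *AtVEX1* fell by 2.25, the actin genes *ACT12* and *ACT11* by 1.38 and 0.61, and the tubulin gene *TUA1* by 0.83. The median was −1.11 with a camera adjusted p of 6.47e-06 and, with an estimated correlation, an adjusted p = 0.302. By fry the adjusted p was 0.00908. These 4 genes are also in the added pollen list.

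Lists of floral organ identity and flower patterning, flowering time, auxin, meiosis and core histones had 3, 4, 4, 4 and 3 measured members. Their camera adjusted p values were 0.371, 0.371, 0.571, 0.571 and 0.343. The first list was measured through *SPL*, *UFO* and *SPT* alone. With so few members these tests leave a change of such genes open. Over the 42 measured genes of all fixed lists, 8 fell and 0 rose by limma over all probe sets. At an unadjusted p under 0.05 there were 11 lower and 7 higher, and 16 passed when adjusted over the list alone, 10 lower and 6 higher. Many of these lists had only 1 or 2 measured members. For them adjustment over the list alone leaves the p unadjusted or nearly so. The auxin-conjugating enzyme gene *GH3.3* fell by 0.65, with an adjusted p of 0.0253 that rose to 0.0593 after median centring and to 0.0944, 0.102 and 0.105 without *top1α-2* replicate 2, wild-type replicate 3 and *top1α-2* replicate 3.

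The 6 genes that were higher only when adjusted over the list alone had small differences and came from lists of 1 or 2 measured members. *TOP3A*, of another topoisomerase, had a log2 change of 0.66 and a limma adjusted p of 0.101 over all probe sets. The mitotic kinase genes *AUR1* and *AUR2* had changes of 0.28 and 0.25, the replication gene *PRL* 0.30, the leaf polarity gene *PHV* 0.30 and the Rubisco activase gene *RCA* 0.47. *YAB3*, also of organ polarity, had a change of −0.33 and passed over its list alone. *TOPII*, the gene of topoisomerase 2, had a change of 0.22 with a limma adjusted p of 0.273. *UFO* and *SPT*, of flower patterning, had changes of −0.70 and 0.09, and *GI*, of flowering time, 0.17.

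Genes near the mutated locus were called about as often as others. Within 5000 AGI number units of AT5G55300, in the locus order of TAIR10.1, 41 of 515 genes were called, and elsewhere in the nuclear genome 1065 of 12750 were. The odds ratio was 0.949, with a 95% interval from 0.668 to 1.32, and Fisher's exact test gave a two-sided p of 0.808.

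Of the calls, 168 higher and 878 lower probe sets changed at least 2-fold, and 28.3% of all probe sets had groups that did not overlap, against 10% by chance for 3 against 3. After median centring the calls were 1153 higher and 1167 lower, in place of 773 and 1334. The count of higher probe sets was 357, 411 and 373 without *top1α-2* replicate 1, 2 and 3, and with a variance prior without the trend there were 209 higher and 633 lower, with the plain test per probe set 30 and 20.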

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

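The tests of array scaling, of pollen content and pollen share with each list set against photosynthesis and of linkage to the mutated locus were chosen after the results were seen.

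A signal in control probe sets differed between the genotypes. The difference between the 3′ and 5′ probe sets of an actin control was 3.57 ± 0.19 in the wild type and 4.03 ± 0.07 in *top1α-2* (SD, n = 3), 0.46 higher in the mutant with no overlap. Of 6 such ratios compared, 1 was separated in this way, against 10% by chance, and those of GAPDH, ubiquitin and a second actin control overlapped. The second actin control had means of 0.70 in the wild type and 0.74 in *top1α-2*. A general difference in RNA quality is therefore not shown by these ratios.

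Transcripts of the pollen and pollen tube list were lower on all 3 *top1α-2* arrays. Array scaling is argued against, since after quantile normalization the median change of the list was still −1.52. The 22 genes had an estimated inter-gene correlation of 0.55 between arrays of a genotype, pooled over both genotypes. The highest value among 1000 random lists matched on signal was 0.20. Array means ran from 7.66 to 8.69 in the wild type and from 6.52 to 6.62 in *top1α-2*. The joint movement was thus seen mainly in the wild type. Random lists were not matched on tissue, and the nuclear photosynthesis list had 0.67. The correlation cannot single out pollen content, though a different pollen content of the harvested inflorescences may contribute. The anther and tapetum list had an estimated correlation of −0.04, 4 of its 11 members are also in other added lists, and it fell without such joint movement. Whether *top1α-2* flowers form less pollen or the flowers sampled differed in stage stays open, since both follow genotype here.

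*QQS* and AT1G58025 were higher on all 3 *top1α-2* arrays by 4.98 and 4.09 on the log2 scale. By their locus codes both genes lie on other chromosomes than *TOP1α*, so 0 of the 2 lie within 10000 AGI number units of AT5G55300. A segment linked to *TOP1α* therefore does not carry them, which the codes gave in advance. This count cannot address background differences elsewhere in the genome. Such differences and an effect of the genotype on these loci stay open and were not tested further.

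Of 25 nuclear photosynthesis genes 6 rose in *top1α-2*, and the list passed by camera with its preset correlation, not with an estimated one at an adjusted p of 0.405, nor by fry at 0.0826. Whether a lower pollen share that raised all other transcripts alike is the whole cause depended on the reference. Relative to 34 regulators of shoot, flower and organ development the list rose by 0.66, with a pooled SD of 0.26 and no overlap. With this reference, which was chosen after the results were seen, the values argue against that explanation. The regulators themselves had a mean change of −0.16, where this explanation needs a rise, and without members of the anther or pollen lists the difference was 0.63. Their own fall, at a fry adjusted p of 0.0164, enlarges the difference. Relative to chromatin genes and RNA polymerase subunits it was 0.53 and 0.40, without overlap but under 2 pooled SDs of 0.33 and 0.22, and relative to the cell division list it was 0.26 with a pooled SD of 0.22 and overlap, so part of the rise may be shared with other transcripts, and more green tissue in the mutant sample or an effect of genotype stay open. Wild-type replicate 1 alone is argued against, since without it the median was still 0.34. The other wild-type arrays, at 11.37 and 11.28, also lay below the *top1α-2* arrays at 11.60 to 11.76. Without wild-type replicate 1 the camera adjusted p at the preset correlation was 7.81e-09, in a range of 4.08e-13 to 7.81e-09 over the arrays left out. That p treats the 25 genes as nearly independent, while their estimated correlation was 0.67, so it adds no support here.

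The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 773 higher and 1334 lower probe sets by limma, and the highest of the other splits was 0 in either direction, so 1 of the 10 splits gave as many in each case. At an unadjusted p under 0.05 the real split gave 5292 probe sets and the other splits 415 to 824. Each other split mixes the genotypes, so the genotype difference adds to its spread within groups and can lower its counts. The other splits are therefore no reference free of a genotype difference. Of the fixed lists 1 changed, the highest of the other splits was 1, and 2 of the 10 splits gave as many. Of the added lists 9 changed, the highest of the other splits was 6, and 1 of the 10 gave as many.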

How the results depend on the processing

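Counts over named genes alone were chosen after the data were seen, and the added lists after the annotation was seen and before any test was run. Of the counts of probe sets, higher calls were 357 to 794 and lower calls 975 to 1335 over the arrays left out in turn. They were 209 and 633 with a variance prior without the trend, 30 and 20 with the plain test per probe set, 168 and 878 at an adjusted p under 0.05 with at least 2-fold change, and 395 and 723 over named genes. Higher calls were 1284 at an adjusted p under 0.1 and 198 at an unadjusted p under 0.01 with at least 2-fold change. In 0 of the 12 settings that changed the values or arrays was a limma call in the opposite direction from the main comparison. Wild-type and mutant arrays of the same number did not deviate together, with correlations of 0.03, 0.00 and 0.02, and 3 of 6 arrays correlated best with their own number. With the replicate number as a block there were 748 higher and 1342 lower probe sets, 9 added lists and 1 fixed list. With an estimated correlation camera called 0 fixed and 0 added lists, 0 and 4 at an unadjusted p under 0.05, and fry called 1 and 7. The estimate was −0.04 for anther and tapetum and for cell division, 0.01 for SWEET transporters and 0 for cold and dehydration. These lie at about the preset 0.01 or below it, so for these lists a higher correlation did not end the call. The medians do not depend on the set test: those lost with an estimated correlation were −1.11 for maturing pollen, −1.65 for pollen and pollen tube, 0.51 for nuclear photosynthesis, 0.40 for plastid-encoded genes, −1.19 for anther and tapetum, −0.46 for SWEET transporters and for flavonoid synthesis, 0.23 for cell division, −0.59 for cold and dehydration and −0.38 for mitochondrion-encoded genes. By fry the nuclear photosynthesis, plastid-encoded and flavonoid lists were lost, and regulators of shoot, flower and organ development passed, lower at an adjusted p of 0.0164. Without the dimmest 50% of probe sets 5 added lists passed, and those lost had medians of −0.10 for mitochondrion-encoded genes, 0.23 for cell division, −0.30 for cold and dehydration and −0.61 for flavonoid synthesis, with fewer members measured. With a pseudocount of 16 flavonoid synthesis had −0.43 and an adjusted p of 0.0503. Over the arrays left out, with fewer samples, the median was 0.24 to 0.52 for plastid-encoded genes, lowest without wild-type replicate 3, and 0.34 to 0.60 for nuclear photosynthesis, lowest without wild-type replicate 1, and both kept their call. It was −0.73 to −0.34 for mitochondrion-encoded genes, lost without wild-type replicates 1 and 2 and *top1α-2* replicates 2 and 3. It was −0.68 to −0.46 for cold and dehydration, lost without *top1α-2* replicate 2, and −0.59 to −0.35 for flavonoid synthesis, lost without wild-type replicate 1 and *top1α-2* replicates 2 and 3. Near the mutated locus the odds ratio was 1.21 in a window of 2500 AGI number units and 0.996 in one of 10000. For causes not given by fewer genes or samples, the cause was not tested. Of the 32 called genes chosen by the rule, GH3.3 lost its call in 4 settings and the other 31 kept theirs in each setting that measured them, where 10 were not measured without the dimmest 50%, and AMS passed without the dimmest 25%. Of 89 other called genes of lists and neighbours 49 lost their call in at least 1 setting, mostly without a single array, where fewer samples are tested, and 0 changed sign. A second probe set of *TOP1α* and the gene length trend were not run.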

Other observations

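The tests of neighbouring genes were chosen after the result was seen.

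In other gene families single members were called, and none of these lists passed by camera. Over all 13356 named genes, for comparison, 395 were higher and 723 lower. Among 27 expansin and xyloglucan hydrolase genes, which loosen cell walls, 5 rose and 2 fell, with a camera adjusted p of 0.491. *EXPA20* rose by 1.76, *EXLB1* by 1.18, *XTH32* by 1.10 and *XTH16* by 0.72, while *EXPB5* fell by 2.07 and *EXPA8* by 0.99. *EXLB1* lost its call when any of 5 of the 6 arrays was left out, at a limma adjusted p of up to 0.124. The other expansin and xyloglucan hydrolase genes named here kept theirs. Of 11 RALF-like signalling peptide genes, the neighbours *RALFL25* and *RALFL26* fell by 2.39 and 2.17, with a camera adjusted p of 0.227 for the list. Of 20 auxin genes, *GH3.17* and *IAGLU*, both of auxin conjugation, fell by 0.70 and 1.12, besides *GH3.3*, and the list had a camera adjusted p of 0.23. *IAGLU* lost its call without wild-type replicate 3, at a limma adjusted p of 0.0522. Among 47 UDP-glycosyltransferase genes 1 rose and 4 fell, with a camera adjusted p of 0.227.

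The petal size regulator *BPEp* fell by 1.69, and of 34 regulators of shoot, flower and organ development it and *SPL* were called, with a camera adjusted p of 0.283 and a fry adjusted p of 0.0164 toward lower values. Of 9 ovule and female gametophyte genes *DD46* fell by 1.63, with a camera adjusted p of 0.23. Of 989 annotated pseudogenes 5 rose and 7 fell, with a camera adjusted p of 0.50. Among them AT1G35650 rose by 3.77 and AT1G59265 by 3.27, from wild-type means of 3.52 ± 1.36 and 3.2 ± 1.41 (SD, n = 3), while AT2G15650 fell by 3.88. All 3 were read by probe sets that are shared by design between similar sequences. AT1G59265 lost its call without *top1α-2* replicate 2 or 3, at limma adjusted p values of 0.0779 and 0.0682. In lists of DNA repair, recombination and topoisomerases, of meiotic recombination, of nuclear RNA polymerase subunits, of flowering time and of defence, 0 genes were called by limma, with 2, 1, 0, 1 and 4 at an unadjusted p under 0.05. Their camera adjusted p values were 0.139, 0.841, 0.283, 0.452 and 0.452. For chromatin and histones, heat shock and organelle RNA editing the camera adjusted p values were 0.783, 0.571 and 0.227.

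Genes that fell lay beside each other more often than a chance order gives. In 74 cases neighbouring named loci on a chromosome both fell, against a mean of 38.9 and a highest value of 62 in 10000 shuffles of the calls, with a permutation p of 1e-04, the smallest these shuffles can give. The longest runs were 5 loci from AT1G23560 to AT1G23600, with log2 changes from −2.21 to −1.21, and 5 loci from AT3G28770 to AT3G28840, with changes from −2.69 to −2.53. Both run lengths include unstable calls. AT3G28770 lost its call when any of 5 of the 6 arrays was left out, at a limma adjusted p of up to 0.162. AT1G23560 and AT1G23580 lost theirs without any of 3 and 2 arrays, at up to 0.0813 and 0.0698. For genes that rose the count was 14 pairs, within the shuffles' middle 95% of 5 to 18, and the pair of kinase genes AT5G11400 and AT5G11410 rose by 3.60 and 3.26. AT5G11400 lost its call without *top1α-2* replicate 2, at a limma adjusted p of 0.0517. A candidate explanation is that tandem copies of genes active in pollen fell together, in part by shared signal between similar probe sets, and this was not tested beyond the 74 pairs.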
